A study of Mus musculus with 10 samples.

How the data were processed

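The series holds 10 samples of mouse embryos at 15 dpc: wild type gallbladder, Sox17+/- gallbladder and wild type cystic duct of ICR, and wild type and Sox17+/- gallbladder of B6, each with 2 biological replicates per the series design. Per the labels' protocols, RNA was extracted with Trizol and biotinylated cRNA was made from 10 ug of total RNA. The deposited values are log2 signals per probe set, per the labels; the background and normalization methods behind them are not given in the sources used here. Groups were read from the sample titles and label fields. The label tags for stage and genotype are swapped in the sample records, and the values under them were used. No label gives an animal, a litter or an array batch, and no other column per sample was present (0).

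Of 45101 probe sets, 64 controls were left out, 34958 map to 1 gene in the platform table, 932 to several and 9211 to none. Only those with 1 gene were used, and Entrez identifiers of 34754 of them were found in the reference gene table (assembly GRCm38.p6, used for gene names and for which genes neighbour Sox17) and 204 were not. Each of 18194 genes was read by the probe set with the highest mean, with cross-hybridizing types (names in _x_at) used only where no other was present. Genes under the 30th percentile of mean log2 signal (4.47) were left out, which left 14696. Sample medians ran from 5.51 to 6.07 and interquartile ranges from 2.75 to 3.85, a spread above the tolerance of 0.2 log2 set before the data were examined, so the samples were quantile normalized. The values ran from 2.20 to 15.15 and were already in log2, so no floor was set.

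A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3) with empirical Bayes variances and a mean-variance trend. It has 5 residual degrees of freedom, and 7.95 in total with the prior. Contrasts were Sox17+/- minus wild type gallbladder over both strains, in ICR and in B6, the difference of these (B6 minus ICR), cystic duct minus gallbladder in ICR wild type, and B6 minus ICR in wild type gallbladder. P values were adjusted by Benjamini-Hochberg across all tested genes, and again over each list alone, with a threshold of 0.05. Of the probe sets with no listed gene, 4403 were among 31526 probe sets tested on their own; 0 of them passed for a genotype effect, 207 for cystic duct against gallbladder and 172 for strain.

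Gene lists for cell types and pathways were fixed before the data were examined: 23 lists with 438 entries, of which 366 were measured. Lists with at least 5 measured genes were tested, 22 in all; the list of sex-linked genes was not. Camera was run with its preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated per list; p values were adjusted over the lists of a comparison. Fry, a rotation test of the same lists, was run beside it without deciding a call. The 100 genes highest and the 100 lowest in cystic duct among those called were tested the same way against the genotype effects. Because the ICR contrasts share the wild type samples, 100 draws of simulated unchanged groups gave the values that sharing produces where no gene differs. Named genes follow a rule fixed before the data were examined: Sox17, then up to 10 per direction with the largest change among those that passed and were separated in all samples, 3 per direction by p where none passed, and up to 4 per list by p. Predicted or numbered gene models were skipped. Other genes named here were chosen after their values were seen.

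Alternatives, changed 1 at a time, were the values as deposited, centring on medians, no filter or the 50th percentile, the mean of a gene's probe sets or every probe set on its own, no trend, array weights, only the compared groups, the replicate number as a block, signatures of 50 or 200 genes, and leaving out each sample. Leaving out a sample leaves 1 in its group, which is then assumed to vary like the other groups. The scripted steps were tested on simulated data with 200 changed genes of 14696. For the genotype effect over both strains, 68.8% of changes of 1 log2 unit, 97.4% of 2 and 100% of 3 were recovered with 10 false calls. For ICR genotype these were 31.9%, 92.2% and 96.9% with 6 false calls, and for cystic duct against gallbladder 25.8%, 87.8% and 96.7% with 8. The simulation drew each gene independently and with the same spread in all groups. The real cystic duct pair had a median difference of 0.54 log2, against at most 0.19 in the gallbladder pairs. These shares therefore check the steps and do not give the recovery in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.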

Results

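Gallbladders and cystic ducts of mouse embryos at 15 days post coitum (dpc) were profiled on Affymetrix arrays carrying 45101 probe sets, groups of short oligonucleotides that each read a transcript or several related ones. The 10 samples formed 5 groups of 2 biological replicates. Wild type and Sox17+/- gallbladders came from ICR, an outbred stock, and from C57BL/6 (B6), an inbred strain. Wild type cystic duct, the tube that joins the gallbladder to the bile duct, came from ICR. Sox17 encodes a transcription factor of the endoderm, the embryonic layer that lines the gut and its glands, and Sox17+/- embryos carry 1 altered copy. The comparisons address how Sox17+/- gallbladder differs from wild type in each strain, whether the strains differ in this, how cystic duct differs from gallbladder, and whether Sox17+/- gallbladder shifts towards cystic duct. As deposited, the log2 signals of a sample had a median of 5.51 to 6.07, and the number of arrays limits the precision. After quantile normalization, replicates of the 4 gallbladder groups correlated at r = 0.966 to 0.996 across 14696 genes, while the cystic duct pair reached r = 0.898 and differed by over 1 log2 unit in 3565 genes.

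Sox17 transcript was lower in Sox17+/- gallbladder of both strains. On the probe set that reads the gene here, the log2 signal was 9.38 ± 0.20 in wild type and 7.77 ± 0.17 in Sox17+/- gallbladder of ICR (SD, n = 2), and 9.16 ± 0.18 and 7.97 ± 0.08 in B6. Over both strains the Sox17+/- level was 37.8% of wild type by limma (95% interval 28.8 to 49.7, adjusted p = 4.5e-05 over the 2 probe sets). The other probe set, of a type prone to cross-hybridization, gave 34.7% (95% interval 25.5 to 47.3, limma adjusted p = 4.5e-05). Sox17 stood at 32.8% of wild type in ICR and 43.7% in B6 on the first probe set, and the difference between the strains did not pass (limma adjusted p = 0.274). Among all genes tested, Sox17 did not pass in the fit of all samples (limma adjusted p = 0.0542). With the gallbladder samples alone, a fit whose variance leaves out the cystic duct pair, it passed (limma adjusted p = 0.00403). The labels do not describe the allele, so whether either probe set lies in the altered part of the gene is not known here. Among 17 measured genes that flank Sox17 in the assembly GRCm38.p6, 0 passed in limma over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and their median change was -0.04 log2 (camera adjusted p = 0.269).

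Over both strains, 5 genes fell and 3 rose in Sox17+/- gallbladder. The largest falls were those of Shh, the secreted ligand of the Hedgehog pathway, and Cited1, a transcriptional coregulator. Shh fell 8.53-fold, from 11.70 to 8.46 log2 units in ICR and from 12.26 to 9.31 in B6 (n = 2 per group). Cited1 fell 8.52-fold, from 10.85 to 7.59 in ICR and from 10.66 to 7.75 in B6. Hhip, which encodes a membrane protein that binds Hedgehog ligands and is itself a target of the pathway, fell 3.24-fold. Pmch, the precursor of melanin-concentrating hormone, fell 4.21-fold, and Igfbp2, a binding protein of insulin-like growth factors, fell 2.60-fold. Cym, which encodes the stomach protease chymosin, rose 7.17-fold, Wfdc18, a small secreted protein, rose 4.32-fold and Lurap1l rose 2.94-fold.

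**Figure D1:**
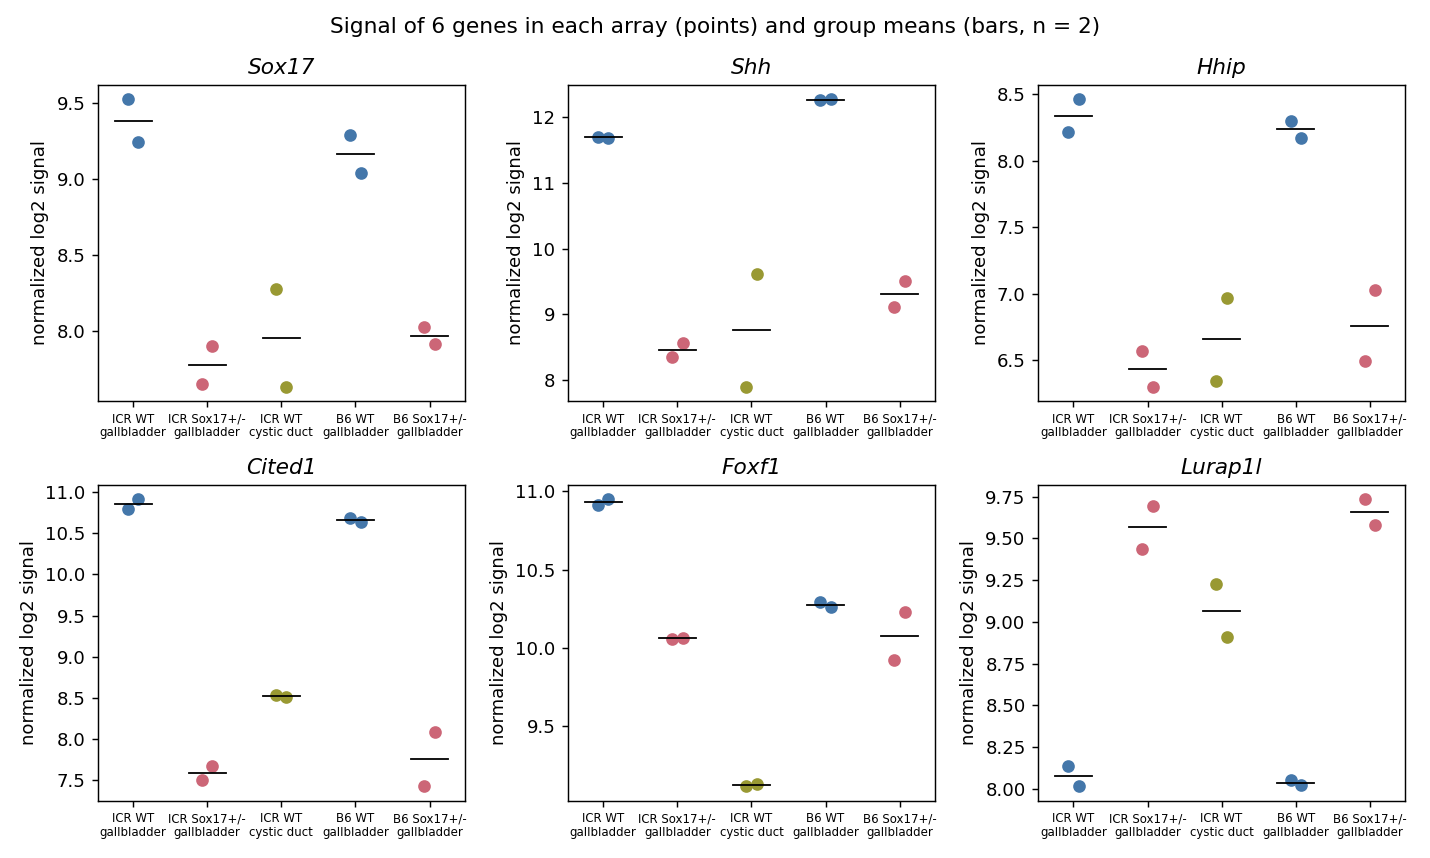
Normalized log2 signal of Sox17, Shh, Hhip, Cited1, Foxf1 and Lurap1l in each of the 10 arrays, with points for single samples and bars for the mean of each group (n = 2). For Shh the Sox17+/- gallbladders had means of 8.46 in ICR and 9.31 in B6, against 11.70 and 12.26 in wild type, and the cystic ducts had a mean of 8.76.

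The log2 changes of the 8 genes over both strains were -3.09 (SE 0.32) for Shh, -3.09 (SE 0.15) for Cited1, -2.07 (SE 0.24) for Pmch, -1.69 (SE 0.20) for Hhip, -1.38 (SE 0.13) for Igfbp2, 2.84 (SE 0.32) for Cym, 2.11 (SE 0.23) for Wfdc18 and 1.56 (SE 0.12) for Lurap1l. By limma, the adjusted p was 0.000462 for Cited1, 0.00797 for Lurap1l, and between 0.0345 (Igfbp2) and 0.0488 (Hhip, Pmch, Cym) for the others. Lurap1l stood at 0.84 with the mean of its probe sets and did not pass (limma adjusted p = 0.139). At an unadjusted p under 0.05 limma listed 522 genes, or 3.55% of those tested, fewer than chance alone would give at this threshold. The variance behind these p values takes in the cystic duct pair, which is not compared here. That pair differed by over 1 log2 unit in 3565 genes, so the share does not measure how many genes differ. With the 8 gallbladder samples alone the SE of Shh was 0.099, against 0.32. In ICR wild type gallbladder replicate 1, 521 genes lay over 1 log2 unit below replicate 2 and below all 7 other gallbladder samples. Fits without replicate 2 rest on that sample alone for their group. The count depended on single libraries, and the genes with it. It was 281 without ICR wild type gallbladder replicate 2, of which 269 were higher and 12 lower, 78 and 77 without cystic duct replicate 1 or 2, and 5 without ICR wild type gallbladder replicate 1. It was 3 and 1 without ICR Sox17+/- replicate 1 or 2, 1 without either B6 wild type sample, and 1 and 2 without B6 Sox17+/- replicate 3 or 4. Cited1 passed in all 10 of these fits, Lurap1l in 5, Igfbp2 and Cym in 4, and Shh, Hhip, Pmch and Wfdc18 in 3, with no change of sign. The count was 136 with array weights, 78 with the 8 gallbladder samples alone, 5 without a filter on dim genes, and 2 without a trend in the prior variance or with every probe set tested on its own. With the replicate number as a block it was 1. In the values as deposited the calls were 2 higher and 8 lower.

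Of the 22 gene lists tested over both strains, camera called 7 at its preset correlation and 0 with an estimated one. Of 11 measured Hedgehog pathway genes, 2 fell (Shh and Hhip) and 0 rose, and adjusted over the list alone 3 fell, with Ihh, a further Hedgehog ligand, at -0.80 log2 (SE 0.23). The receptor and target Ptch1 changed by -0.49 (SE 0.19) and the effector Gli1 by -0.47 (SE 0.16), and neither passed. The list was lower by camera with a median of -0.11 log2 (adjusted p = 5.9e-06; adjusted p = 0.305 with an estimated correlation). That median was -0.07 and -0.19 without B6 Sox17+/- replicate 3 or 4, -0.18 without ICR Sox17+/- replicate 1 and -0.17 without ICR wild type replicate 1. Of 18 regulators of the extrahepatic biliary tree, 0 passed over all genes, and 5 did adjusted over the list alone: the endoderm factors Hhex (0.75, SE 0.12), Pdx1 (1.40, SE 0.22) and Sox9 (1.24, SE 0.29) were higher, and Sox17 and the mesenchymal factor Foxf1 (-0.53, SE 0.09) lower. The other probe set of Pdx1 gave 0.04, and with the mean of probe sets Pdx1 stood at 0.72 and Sox9 at 0.73. Their camera adjusted p was 0.0371 (median 0.11 log2; adjusted p = 0.305 with an estimated correlation). This call was lost without ICR wild type gallbladder replicate 2, ICR Sox17+/- replicate 2, B6 wild type replicate 4 or B6 Sox17+/- replicate 3, with an adjusted p of up to 0.382.

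Lists of hepatocyte, skeletal muscle and erythroid genes were higher by camera over both strains, but not each in both. The 20 hepatocyte genes had a median change of 0.70 log2 (camera adjusted p = 4.81e-13; adjusted p = 0.305 with an estimated correlation), 18 of them lay above 0, and Serpina1b, an antitrypsin of hepatocytes, stood at 1.15 (SE 0.21). The 12 skeletal muscle genes had a median of 0.87 log2 (camera adjusted p = 1.33e-09; adjusted p = 0.305 with an estimated correlation), with 12 above 0 and the muscle differentiation factor Myog at 1.11 (SE 0.23). The 14 erythroid genes had a median of 0.75 log2 (camera adjusted p = 2.31e-06; adjusted p = 0.489 with an estimated correlation), with the erythroid factor Klf1 at 1.10 (SE 0.47). Without ICR wild type replicate 2 the erythroid median was 0.43 and Klf1 stood at 0.64, and without B6 Sox17+/- replicate 4 the median was 0.49. Taken by strain, hepatocyte genes did not pass in B6 (median 0.17, camera adjusted p = 0.188) and skeletal muscle genes did not pass in ICR (median 0.42, camera adjusted p = 0.107). Members that passed limma over all genes numbered 0 in each of these 3 lists, with 9, 6 and 2 at an unadjusted p under 0.05, and 1, 1 and 0 rose adjusted over the list alone (Serpina1b and Myog).

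Of 22 contractile genes of smooth muscle, the cell type of the gallbladder wall, 16 lay below 0 and the median change was -0.17 log2 (camera adjusted p = 0.00044; adjusted p = 0.489 with an estimated correlation). Cckar, the cholecystokinin receptor that drives gallbladder contraction, stood at -1.49 (SE 0.38), the smooth muscle myosin Myh11 at -0.62 (SE 0.17) and the actin-binding Cald1 at -0.28 (SE 0.08). The other probe set of Myh11 gave 0.10, and the mean of both -0.26. In limma 0 of the 22 passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list's call was lost without ICR wild type gallbladder replicate 2 (adjusted p = 0.135, camera). The 17 genes of cholangiocyte transport had a median of 0.05 log2 (camera adjusted p = 0.0371; adjusted p = 0.305 with an estimated correlation), with the phospholipid transporter Abcb4 at 0.72 (SE 0.21), 0 passing limma by either adjustment, and 2 at an unadjusted p under 0.05. That call was lost without either cystic duct sample, without ICR wild type or Sox17+/- replicate 2, and without B6 wild type replicate 4 or Sox17+/- replicate 3, with an adjusted p of up to 0.417. Its median was 0.02 and 0.14 without ICR wild type replicate 2 or 1, 0.10 and 0.11 without ICR Sox17+/- replicate 1 or 2, 0.11 and 0.09 without B6 wild type replicate 3 or 4, and 0.08 and 0.09 without B6 Sox17+/- replicate 3 or 4.

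The other lists did not pass over both strains. Among 19 biliary epithelium genes, 0 passed over all genes in limma and 4 had an unadjusted p under 0.05. Adjusted over the list alone the tetraspanin Tspan8 (1.70, SE 0.31) and the cadherin Cdh6 (0.97, SE 0.15) were higher. That list had a median of -0.01 against a mean of 0.16 and an upward test (camera adjusted p = 0.311). Median changes were 0.01 for fibroblast and matrix, 0.17 for mesothelium, 0.14 for immediate early and heat shock, 0.12 for endothelium, 0.08 for pancreas, 0.04 for leukocyte, 0.04 for cell cycle, 0.04 for Notch, 0.06 for neural, -0.01 for inflammation, -0.01 for interferon, 0.07 for Wnt and 0.12 for intestinal epithelium genes, with camera adjusted p between 0.0591 and 0.944. Mean, median and test differed in sign for intestinal epithelium (mean -0.20), which holds Shh, and for the fibroblast, Wnt and interferon lists. The inflammation regulator Tnfaip3 stood at -0.76 (SE 0.13), lower adjusted over the list alone, and at -0.46 with the mean of its probe sets.

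In ICR alone, Cited1 fell 9.64-fold (-3.27 log2, SE 0.21, limma adjusted p = 0.00442), and it was the only gene that passed. An unadjusted p under 0.05 was reached by 776 genes, or 5.28%, near the share that chance alone would give. The variance here, too, takes in the cystic duct pair, so this share does not measure how many genes differ. Shh stood at -3.24 (SE 0.46), Hhip at -1.91 (SE 0.28), Sox17 at -1.61 (SE 0.24) and Foxf1 at -0.87 (SE 0.13), each with a limma adjusted p of 0.219. Hepatocyte transcripts were higher, with a median of 1.27 log2 and 19 of 20 genes above 0 (camera adjusted p = 5.45e-17; adjusted p = 0.247 with an estimated correlation). Serpina1b stood at 2.00 (SE 0.30), the apolipoprotein Apoa2 at 3.03 (SE 0.72), transthyretin (Ttr) at 1.43 and the fibrinogen chain Fgg at 1.74. Without ICR wild type replicate 1 Apoa2 stood at 1.81 and Ttr at 0.76, Ttr stood at 0.57 with the mean of its probe sets, and the list median was 0.77 without wild type replicate 2 and 0.79 without Sox17+/- replicate 1. In limma 0 of the 20 passed over all genes, 13 had an unadjusted p under 0.05, and 5 rose adjusted over the list alone. The Hedgehog list had a median of -0.18 log2 (camera adjusted p = 8.49e-06; adjusted p = 0.247 with an estimated correlation), and of -0.33 and -0.31 without replicate 1 of wild type or of Sox17+/-. Adjusted over the list alone 5 of its 11 genes fell, Shh, Hhip, Ihh (-1.09), Gli1 (-0.84) and Ptch1 (-0.82), and over all genes 0 passed limma, with 5 at an unadjusted p under 0.05. With the mean of probe sets Shh stood at -1.98 and Ptch1 at -0.52. Erythroid genes had a median of 0.63 (camera adjusted p = 0.00441; adjusted p = 0.589 with an estimated correlation) and mesothelium genes one of 0.34 (camera adjusted p = 0.0163; adjusted p = 0.589 with an estimated correlation). Both of these calls were lost without ICR Sox17+/- replicate 1 or wild type replicate 2, with adjusted p of up to 0.804 and 0.675. Without ICR wild type replicate 1 or 2 the medians were 1.00 and 0.18 (erythroid) and 0.59 and 0.16 (mesothelium), and without Sox17+/- replicate 1 or 2 they were 0.40 and 1.07 and -0.02 and 0.61. The gene count was 377 without ICR wild type gallbladder replicate 2, of which 372 were higher and 5 lower, 21 without either cystic duct sample, 2 without ICR wild type replicate 1, and 0 without either ICR Sox17+/- sample, and it was 0 with each sample centred on its median. With the replicate number as a block 0 genes passed. With the values as deposited the median of all genes in this comparison was -0.16 log2. The 3' minus 5' signal of Gapdh, a measure of RNA integrity, was 0.60 and 0.93 log2 in wild type and 0.43 and 0.60 in Sox17+/- gallbladder.

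In B6 alone, Cited1 fell 7.53-fold (-2.91 log2, SE 0.21, limma adjusted p = 0.0108), again as the only gene that passed. An unadjusted p under 0.05 was reached by 192 genes, or 1.31%, fewer than chance alone would give. As in ICR, this share rests on a variance that takes in the cystic duct pair and does not measure how many genes differ. Shh stood at -2.95 (SE 0.46) and Hhip at -1.48 (SE 0.28), each lower adjusted over the list alone. The Hedgehog list had a median of -0.06 log2 (camera adjusted p = 0.00442; adjusted p = 0.482 with an estimated correlation). All 12 skeletal muscle genes lay above 0, with a median of 1.27 log2 (camera adjusted p = 6.02e-21; adjusted p = 0.199 with an estimated correlation). The embryonic myosin Myh3 stood at 3.22 (SE 1.00), the myosin light chains Myl1 at 2.04 and Mylpf at 2.00, and Myog, which passed adjusted over the list alone, at 1.40. Their list median, relative to wild type, was 2.20 in B6 Sox17+/- replicate 3 and 0.55 in replicate 4. Without replicate 3 or 4 the list's log2 change was 0.57 and 2.20, with Myh3 at 1.25 and 5.17, Myl1 at 0.76 and 3.32 and Mylpf at 0.73 and 3.27. Cnn1, of the smooth muscle list, stood at -0.31 and -1.07 without wild type replicate 3 or 4. Erythroid genes had a median of 0.71 (camera adjusted p = 1.44e-06; adjusted p = 0.482 with an estimated correlation). Of the 22 smooth muscle genes 18 lay below 0, with Cnn1 at -0.69, Myh11 at -0.61 and a median of -0.19 (camera adjusted p = 7.73e-05; adjusted p = 0.482 with an estimated correlation). The biliary regulators had a median of 0.09 (camera adjusted p = 0.00477; adjusted p = 0.199 with an estimated correlation), with Hhex at 0.83, Pdx1 at 1.19 and Sox9 at 1.42 higher and Sox17 lower adjusted over the list alone. The other probe set of Pdx1 gave -0.01, and with the mean of probe sets Pdx1 stood at 0.59, Sox9 at 0.75 and Myh11 at -0.31. Endothelium genes had a median of 0.14 (camera adjusted p = 0.0163; adjusted p = 0.482 with an estimated correlation). Over all genes 0 members of these 6 lists passed limma, with 7 of skeletal muscle, 4 of the regulators, 2 of Hedgehog, 1 of smooth muscle and 0 of the other two at an unadjusted p under 0.05. Without B6 Sox17+/- replicate 4 the smooth muscle (adjusted p = 0.0695) and erythroid (adjusted p = 0.202) calls of camera were lost, and without replicate 3 the Hedgehog call (adjusted p = 0.0724). The call of the regulators was lost without B6 Sox17+/- replicate 3 or wild type replicate 4, and that of endothelium without Sox17+/- replicate 3 or wild type replicate 3 (camera adjusted p of up to 0.276 and 0.761). Without Sox17+/- replicate 3 or 4 the erythroid median was 1.13 and 0.30 and the Hedgehog median 0.05 and -0.23. Without wild type replicate 3 or 4 the Hedgehog median was -0.12 and -0.02 and that of the regulators 0.15 and 0.06. The regulators' median was 0.20 without Sox17+/- replicate 4 and the endothelium median 0.06 without replicate 3. The gene count was 103 with array weights, 49 with the B6 samples alone and 5 without either cystic duct sample. It was 2 without B6 Sox17+/- replicate 4, 0 without either B6 wild type or any ICR gallbladder sample, and 0 with each sample centred on its median. With the replicate number as a block 0 genes passed. The 3' minus 5' signal of Gapdh was 0.00 and 0.16 log2 in wild type and 0.21 and 0.30 in Sox17+/- gallbladder.

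**Figure D2:**
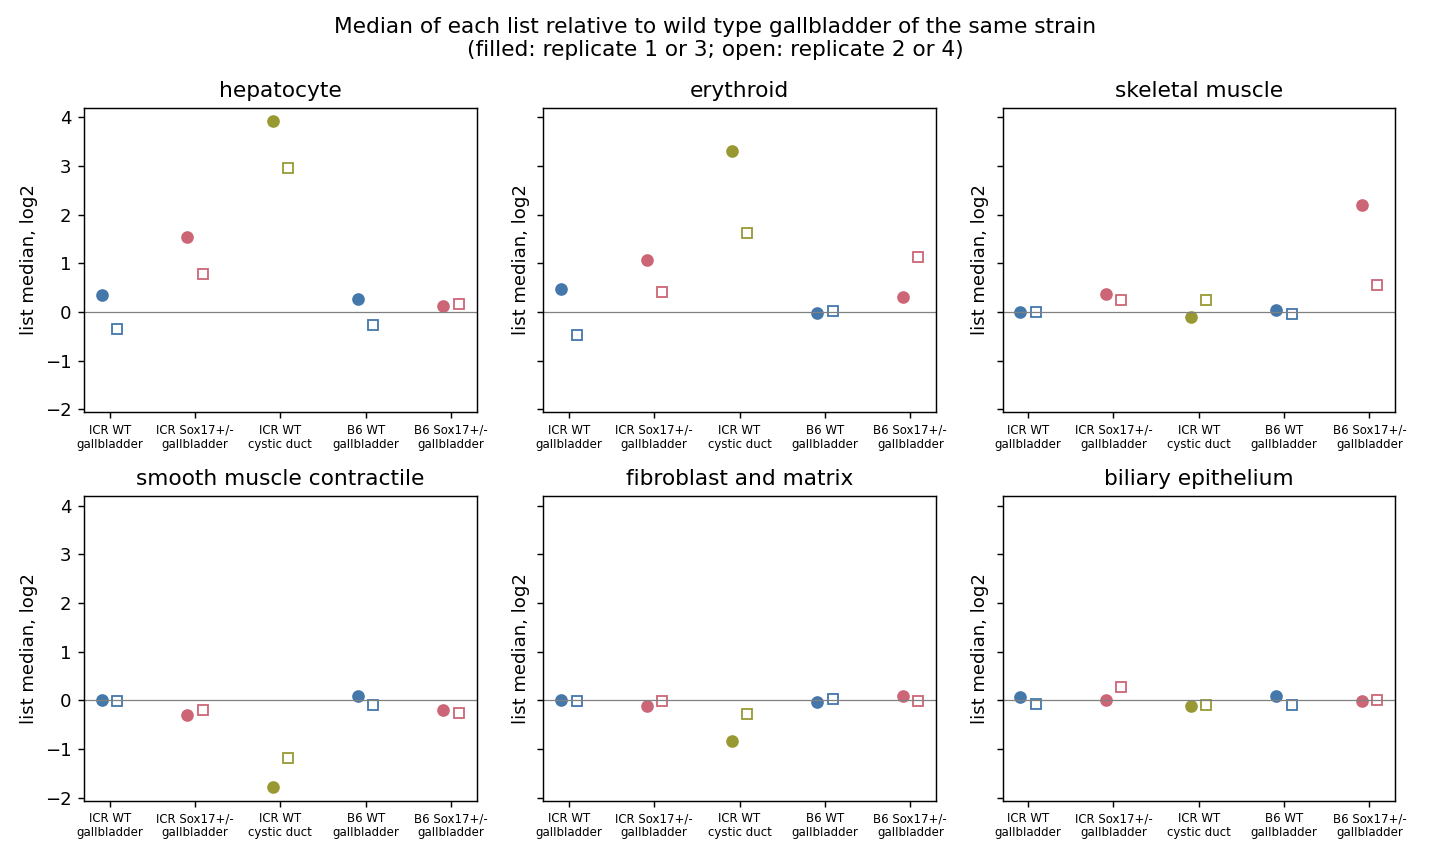
Median log2 signal of 6 gene lists in each library, relative to the mean of wild type gallbladder of the same strain; filled points are replicates 1 and 3 and open points replicates 2 and 4. Skeletal muscle genes stood at 2.20 and 0.55 in the B6 Sox17+/- gallbladders, and hepatocyte genes at 1.53 and 0.79 in the ICR Sox17+/- gallbladders and at 3.91 and 2.96 in the cystic ducts.

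The genotype effects of the strains shared direction for the genes with the smallest p. Of the 50 genes with the smallest p in ICR, 48 had the same sign in B6, and of the 50 in B6, 49 had the same sign in ICR; over all genes 54.2% did. Across genes the log2 changes correlated at r = 0.270 and rho = 0.167, where genes are not independent replicates, against 0.00 on average in simulated unchanged groups. The correlation was 0.132 without ICR wild type gallbladder replicate 2 and 0.387 without replicate 1. Cited1 was called in both strains, against 6.8e-05 genes for independent lists.

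**Figure D3:**
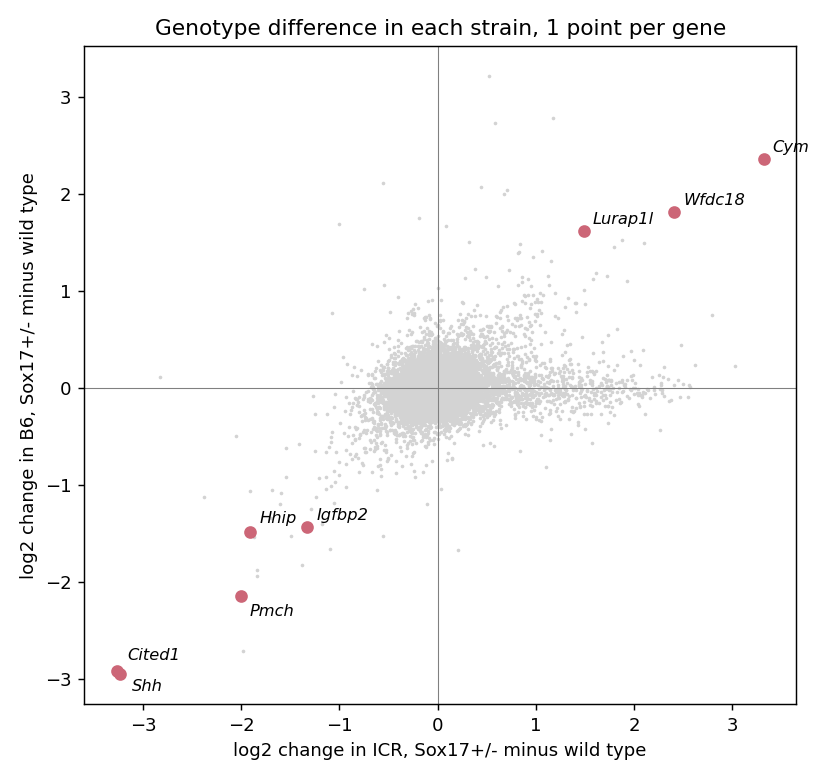
Log2 change from wild type to Sox17+/- gallbladder in ICR (horizontal) and B6 (vertical), 1 point per gene for 14696 genes, with the 8 genes called over both strains marked. The marked genes lie in the same direction in both strains, from -3.09 for Shh and Cited1 to 2.84 for Cym over both.

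No gene passed the test of the difference between the strains' genotype effects: limma called 0. An unadjusted p under 0.05 was reached by 151 genes, or 1.03%, fewer than chance alone would give. This share, too, rests on a variance that takes in the cystic duct pair. Among the genes with the smallest p were Foxf1 (0.67 log2, B6 minus ICR), the cohesin subunit Rad21 (0.58) and Serinc3 (0.66), and in the other direction the plasma protease inhibitor Pzp (-2.39), the annexin Anxa10 (-1.88) and Ywhab (-0.62), with limma adjusted p of 1.00. Other probe sets of Foxf1, Rad21, Serinc3 and Ywhab disagreed in sign, and with the mean of probe sets these stood at 0.32, 0.34, 0.00 and -0.39. Among the lists, the genotype effect on hepatocyte genes was lower in B6 than in ICR (median -1.03 log2, camera adjusted p = 7.49e-14; adjusted p = 0.541 with an estimated correlation) and that on skeletal muscle genes higher (1.11, camera adjusted p = 7.39e-06; adjusted p = 0.541 with an estimated correlation). The effect on Hedgehog genes was higher in B6 (0.27, camera adjusted p = 0.0124; adjusted p = 0.541 with an estimated correlation), and that on mesothelium genes lower (-0.37, camera adjusted p = 0.0196; adjusted p = 0.667 with an estimated correlation). In these 4 lists limma called 0 members by either adjustment, with 4, 1, 0 and 1 at an unadjusted p under 0.05. The hepatocyte median was -0.46 without ICR wild type replicate 2, -0.63 without ICR Sox17+/- replicate 1 and -0.67 without B6 wild type replicate 3. The skeletal muscle call of camera was lost without B6 Sox17+/- replicate 3 (median 0.05, adjusted p = 0.301), and the median was 2.12 without replicate 4. The Hedgehog call was lost without ICR wild type or Sox17+/- replicate 2 or B6 Sox17+/- replicate 4, and the mesothelium call without ICR Sox17+/- replicate 1, ICR wild type replicate 2, B6 wild type replicate 3 or B6 Sox17+/- replicate 4, with adjusted p of up to 0.208 and 0.683. The Hedgehog median was 0.16 without B6 Sox17+/- replicate 4, and the mesothelium median -0.06, -0.20, -0.23 and -0.16 in the order of its 4 libraries. Without ICR wild type gallbladder replicate 2 the gene count was 270, all lower in B6, and without ICR wild type replicate 1 or B6 Sox17+/- replicate 4 it was 1. With the values as deposited the median of all genes was 0.15 log2.

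In the fit of all samples limma called 2107 genes between cystic duct and wild type gallbladder of ICR. Of these 842 were higher and 1265 lower in cystic duct, and 1171 differed by over 2-fold. The calls rest on a variance pooled with the gallbladder groups, while the cystic duct pair itself differed by over 1 log2 unit in 3565 genes. With array weights or the compared samples alone 0 genes passed. Plasma proteins and enzymes of the liver led the rises: the apolipoprotein Apoa2 rose 38.2-fold (5.26 log2, SE 0.72), the protease inhibitor Pzp 30.8-fold (4.95, SE 0.39), the cytochrome Cyp2d26 25.1-fold, fetuin (Ahsg) 20.7-fold, and Apoh and the fatty acid transporter Slc27a2 19.5-fold each. Hsd17b13 (4.15 log2), the urea cycle enzyme Arg1 (4.09, or 17.1-fold), Kng1 (4.07) and Spink1 (4.05) followed. The angiotensin receptor Agtr2 fell 13.8-fold (-3.79 log2, SE 0.87), the troponin Tnnt2 13.4-fold (-3.74, SE 0.57) and the homeobox gene Hoxc8 11.1-fold (-3.48). Further falls were those of Cpa6 (-3.32), the serotonin receptor Htr1b (-3.29), the matrix proteins Mfap5 (-3.25), Abi3bp (-3.16), Aspn (-3.06) and Col19a1 (-3.00), and the activin antagonist Fst (-3.11). Limma adjusted p ranged from 0.00138 (Pzp) to 0.0323 (Aspn) over these 20 genes. Of the 10 fits without 1 sample, Agtr2 and Aspn passed in 2, Htr1b in 4 and Mfap5 in 8, and without cystic duct replicate 1 Agtr2 stood at -2.12, Aspn at -1.67, Mfap5 at -2.16 and Hsd17b13 at 2.11. Htr1b, then read by another probe set, stood at 0.07 and -0.37 without ICR wild type gallbladder replicate 1 or 2 and at -0.15 without any of the 4 B6 samples. With the mean of probe sets Apoh stood at 2.41, Hsd17b13 at 2.63, Tnnt2 at -2.17 and Htr1b at -1.72.

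By list, 19 of 20 hepatocyte genes rose, or 20 adjusted over the list alone, with a median of 3.45 log2 (camera adjusted p = 9.74e-18; adjusted p = 0.214 with an estimated correlation). Among them the hepatic regulator Hnf4a changed by 1.94 (SE 0.16), the fibrinogen chain Fgb by 3.91 (SE 0.42) and Serpina1b by 3.43 (SE 0.30). Of 14 erythroid genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 2.40, camera adjusted p = 1.52e-05; adjusted p = 0.527 with an estimated correlation). The erythroid factors Klf1 (3.89, SE 0.66) and Gata1 (3.27, SE 0.54) and the erythropoietin receptor Epor (1.90) rose, and the globin Hbb-b2 fell (-1.86, SE 0.25). Of 21 cell cycle genes 8 rose, or 10 adjusted over the list alone (median 0.64, camera adjusted p = 1.47e-06; adjusted p = 0.411 with an estimated correlation), with Ube2c at 1.56 (SE 0.19) and Cdc20 at 0.98, both of the machinery that ends mitosis. Without cystic duct replicate 1 the cell cycle median was 0.28. The other probe set of Hbb-b2 gave 1.03, with the mean of probe sets Hbb-b2 stood at -0.41 and Hnf4a at 1.21, and Cdc20 stood at 0.60 in the values as deposited. In these settings Hbb-b2 and Cdc20 did not pass (limma adjusted p = 0.17 for each). Of 17 cholangiocyte transport genes 5 rose, or 8 adjusted over the list alone (median 0.65, camera adjusted p = 0.00245; adjusted p = 0.214 with an estimated correlation), among them Abcb4 (2.08, SE 0.30), the aquaporin Aqp8 (3.39, SE 0.58) and the carbonic anhydrase Car2 (2.28). Hepatocyte and erythroid transcripts rose more in the same samples, so this rise cannot be assigned to biliary cells.

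Lists of smooth muscle, Hedgehog, fibroblast and Wnt genes were lower in cystic duct by camera at its preset correlation. Of 22 contractile genes 15 fell, or 17 adjusted over the list alone, with a median of -1.53 log2 (camera adjusted p = 1.36e-08; adjusted p = 0.358 with an estimated correlation). Myh11 changed by -2.67 (SE 0.24), calponin (Cnn1) by -2.79, tropomyosin (Tpm2) by -1.93 (SE 0.15), smooth muscle actin (Acta2) by -1.77 (SE 0.19) and Cald1 by -1.33. Single other probe sets gave 0.49 for Myh11, 0.28 for Tpm2 and 0.41 for Cald1, and with the mean of probe sets Myh11 and Tpm2 stood at -1.09, Acta2 at -1.07 and Cald1 at -0.81. With that mean Myh11 passed, but Tpm2, Acta2 and Cald1 did not (limma adjusted p = 0.123, 0.1005 and 0.076). Of 11 Hedgehog genes 5 fell, or 7 adjusted over the list alone (median -1.08, camera adjusted p = 0.00124; adjusted p = 0.315 with an estimated correlation), Shh by -2.93 log2 (SE 0.46), Hhip by -1.68, Gli1 by -1.66 (SE 0.23), Gli2 by -1.22 and Ptch1 by -1.19. Of 21 fibroblast and matrix genes 7 fell, or 13 adjusted over the list alone (median -0.53, camera adjusted p = 0.00124; adjusted p = 0.685 with an estimated correlation), with the collagen Col5a1 at -1.14 (SE 0.10) and vimentin (Vim) at -1.05. Of 16 Wnt genes 4 fell by either adjustment (median -0.51, camera adjusted p = 0.00743; adjusted p = 0.214 with an estimated correlation), among them the ligand Wnt5a (-2.43, SE 0.22) and the antagonists Dkk2 (-2.22) and Sfrp2 (-1.40). The mean of probe sets put Shh at -1.77, Ptch1 at -0.46 and Col5a1 at -0.66, where Shh passed but Ptch1 and Col5a1 did not (limma adjusted p = 0.148 and 0.084). The lists of Hedgehog (adjusted p = 0.168) and fibroblast genes (adjusted p = 0.370) lost camera's call without cystic duct replicate 1, and those of cholangiocyte transport (adjusted p = 0.0786) and Wnt genes (adjusted p = 0.0881) without cystic duct replicate 2. The fibroblast median was -0.29 and -0.81 without cystic duct replicate 1 or 2, the Wnt median was -0.81 and Dkk2 stood at -1.37 without replicate 1, and the cholangiocyte transport median was 0.23 without replicate 2.

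Some lists of the cystic duct comparison did not pass as sets but held genes that did. Of 18 biliary regulators, 2 rose and 4 fell over all genes, or 4 and 5 adjusted over the list alone: Foxf1 fell by 1.80 log2 (SE 0.13), Sox17 by 1.43 (SE 0.24), Klf6 by 1.14 and Onecut1 by 1.54, and the endoderm factors Isl1 (0.78) and Hhex (0.59) rose. Of 19 biliary epithelium genes 2 rose, Cdh6 (1.28, SE 0.22) and the keratin Krt18 (0.59), and 3 fell, with the keratin Krt19 at -1.15 (SE 0.20), or 3 and 3 adjusted over the list alone. With the mean of probe sets Foxf1 stood at -1.07 and Cdh6 at 0.84, where Cdh6 did not pass (limma adjusted p = 0.108). Hhex and Krt18 stood at 0.23 in the values as deposited and at 0.33 with each sample centred on its median. Among alternatives other than leaving out a sample, Hhex passed in 2 of 9, Krt18 in 3 of 9 and Isl1 in 3 of 7. The neutrophil protein S100a9 (3.60, SE 0.73) and myeloperoxidase (Mpo, 3.17) rose and the macrophage receptor Mrc1 (-0.71) fell among 20 leukocyte genes. Camera's adjusted p was 0.991 for the regulators and for biliary epithelium and 0.201 for leukocytes. Median and mean differed in sign for the regulators (0.02 and -0.11) and for biliary epithelium (-0.16 and 0.04), and both tests pointed down. The cystic duct pair differed most of all replicate pairs, and the sizes of the hepatocyte and erythroid medians differed between the replicates, at 3.91 and 2.96 and at 3.31 and 1.61 log2 above gallbladder. As deposited, cystic duct replicate 2 stood apart. It had the narrowest interquartile range of all samples (2.75 log2, against 3.65 in replicate 1). Its mean rank correlation with the other samples was also the lowest (0.898, against 0.955 for replicate 1, the next lowest). Limma called 4495 genes without cystic duct replicate 2 and 7531 without replicate 1, and 813 and 1119 without ICR wild type gallbladder replicate 1 or 2, the latter with 679 higher and 440 lower. The count was 1113 and 1115 without B6 wild type replicate 3 or 4, 1232 and 1219 without B6 Sox17+/- replicate 3 or 4, and 0 with array weights or with the 4 compared samples alone. The calls were 287 higher and 1603 lower in the values as deposited, where the median of all genes was -0.27 log2, and 391 higher and 1082 lower with each sample centred on its median, where it was -0.16.

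The 100 genes highest and the 100 lowest in cystic duct among those called were then followed in Sox17+/- gallbladder. The B6 libraries are not part of the cystic duct comparison. In B6 the gallbladder-high genes had a median of -0.20 log2 and 81 of 100 lay below 0 (camera adjusted p = 5.83e-18; adjusted p = 0.0199 with an estimated correlation), against 0.00 in simulated unchanged groups (range -0.13 to 0.12). The cystic duct-high genes had a median of 0.23 with 79 of 100 above 0 in B6 (camera adjusted p = 3.42e-07; adjusted p = 0.404 with an estimated correlation), against -0.01 in simulated unchanged groups (range -0.14 to 0.11). That median was 0.04 without B6 wild type replicate 4 and 0.01 without ICR wild type gallbladder replicate 2, with the genes chosen anew in each fit. In ICR the cystic duct-high genes had a median of 1.01 (camera adjusted p = 1.19e-45, and 0.0676 with an estimated correlation). The gallbladder-high genes had one of -0.42 (camera adjusted p = 4.35e-18, and 0.0199 with an estimated correlation). Simulated unchanged groups that share the wild type samples gave 0.42 and -0.42. These groups hold no real difference, so their genes were picked on noise alone. The real gallbladder-high genes had changes of -1.90 to -3.79 log2 in cystic duct. The part that shared samples give to the real medians is therefore not known. Without ICR wild type gallbladder replicate 2 the ICR median of the cystic duct-high genes was 3.26. That fit chose the genes anew, and both the choice and the genotype change then rested on wild type replicate 1 alone. This value is therefore no test of the same genes. The cystic duct-high genes include 13 of the hepatocyte and 6 of the erythroid list, and the gallbladder-high genes 8 of the smooth muscle list. Most cystic duct-high genes, in these lists or not, encode plasma proteins, liver enzymes or blood cell proteins, such as Pzp, Cyp2d26, Plg, F2, Rhag and Nfe2. That set therefore largely reads liver and blood transcripts. Across genes the covariance of the cystic duct effect with the genotype effect was 0.161 in ICR (simulated 0.0516; r = 0.562, simulated 0.499) and 0.0442 in B6 (r = 0.270).

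Wild type gallbladders of B6 and ICR differed in 21 genes, 4 higher and 17 lower in B6. The ribonuclease Ang (4.01 log2), Trim12a (3.86) and the zinc finger gene Zfp874a (3.12) were higher in B6. The hepatobiliary transcription factor Onecut1 was 3.18 log2 units lower (-3.18, SE 0.36, 2 probe sets alike), with the interferon-inducible Ifi202b at -3.35, Tcf24 at -2.94, Tmem87a at -2.66 and Bnc2 at -1.94. Malat1 (-4.68), Pa2g4 (-2.92), Zbtb7a (-2.57), Amer1 (-2.41) and Eif5b (-2.12) were also lower, but each has a probe set of the opposite sign. With the mean of probe sets these 5 stood at -1.57, -0.73, -0.97, -1.12 and -0.20, and Bnc2 at -1.03, and none of them passed in limma. Eif5b, then read by another probe set, stood at 1.01 and 2.31 without ICR wild type replicate 1 or 2. Limma adjusted p ranged from 0.00272 (Tmem87a) to 0.0434 (Tcf24) for the genes named, with 1630 genes at an unadjusted p under 0.05.

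Among the lists of the strain comparison, hepatocyte genes had a median of 0.75 log2 (camera adjusted p = 2.99e-05; adjusted p = 0.761 with an estimated correlation) and leukocyte genes one of 0.30 (camera adjusted p = 0.00121; adjusted p = 0.784 with an estimated correlation), with Lyz2 (1.34), Cd52 (1.76) and S100a9 (3.03) higher adjusted over the list alone. Biliary epithelium (0.20, camera adjusted p = 0.00795; adjusted p = 0.784 with an estimated correlation), erythroid (0.71, camera adjusted p = 0.0207; adjusted p = 0.794 with an estimated correlation), cell cycle (0.23, camera adjusted p = 0.0412; adjusted p = 0.794 with an estimated correlation) and fibroblast genes (-0.11, camera adjusted p = 0.0332; adjusted p = 0.794 with an estimated correlation) followed. Over all genes limma called 0 members of these 6 lists, with 7, 7, 7, 1, 3 and 6 at an unadjusted p under 0.05. No label gives an array batch, and each strain has its own replicate numbers, so strain and batch cannot be told apart. The 3' minus 5' signal of Gapdh was 0.60 and 0.93 log2 in wild type gallbladder of ICR and 0.00 and 0.16 in that of B6, and that of Actb was 0.56 and 1.40 against 0.92 and 1.05. The gene count was 0 without either B6 wild type sample, 3 without either ICR Sox17+/- sample, and 5 and 477 without ICR wild type replicate 1 or 2, the latter with 427 higher and 50 lower. It was 59 and 68 without B6 Sox17+/- replicate 3 or 4, and 614 and 602 without cystic duct replicate 1 or 2. Other fits gave 1195 with array weights, 664 with every probe set tested on its own, 296 with the compared samples alone and 33 with the mean of a gene's probe sets. With the values as deposited 7 genes were higher and 47 lower and the median of all genes was -0.13 log2; with each sample centred on its median 12 were higher and 15 lower and it was 0.18.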

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

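All tests of explanations in this part were chosen after the results they address were seen. A test of the difference between strains flagged 4 gene lists whose genotype effect was not the same in B6 as in ICR. By camera on the difference (B6 minus ICR), medians were -1.03 log2 for hepatocyte, -0.37 for mesothelium, 1.11 for skeletal muscle and 0.27 for Hedgehog genes, with adjusted p = 0.541, 0.667, 0.541 and 0.541 with an estimated correlation, so none of the 4 passes once correlation within a list is estimated. The hepatocyte difference was -0.46 without ICR wild type gallbladder replicate 2.

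Hepatocyte genes were higher in ICR Sox17+/- gallbladder (median 1.27 log2) by camera at its preset correlation, with adjusted p = 0.247 with an estimated correlation. The median stayed at 1.17 in the values as deposited, which argues against the quantile step applied here as the whole source. How the deposited values were normalized is not known, so that step was not tested. The median was 0.77 without ICR wild type gallbladder replicate 2 and 1.68 without replicate 1, which argues against either library alone as the whole source. The 0.77 rests on replicate 1 alone, in which 521 genes lay below all 7 other gallbladder samples. Liver tissue in the dissected samples would bring hepatocyte and erythroid transcripts in their proportion in liver. Hepatocyte genes gained 9.67% and erythroid genes 6.21% of their excess in cystic duct replicate 1, a difference of 3.46 points (95% interval 1.23 to 7.20), and 20.6% and 17.4% of that in replicate 2, a difference of 3.22 points whose wider interval (-12.2 to 10.8) includes 0. Only 1 of the intervals leaves out 0. Both resample genes, which vary together within a list, and not samples, so neither can decide. Carried-over liver and a change in the biliary cells therefore cannot be told apart.

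Skeletal muscle genes were higher in B6 Sox17+/- gallbladder, a tissue with no skeletal muscle of its own, by camera at its preset correlation (adjusted p = 0.199 with an estimated correlation). The list medians of its libraries differed by 1.65 log2, and all 12 genes, including the 9 that differed by over 1 log2 unit, were higher in replicate 3. That is consistent with muscle from the body wall in 1 dissected sample, a reading that the test of the replicates allows but cannot prove. Without replicate 3 the median was 0.57, which passed in camera at the preset correlation, so whether that library accounts for all of it stays open. No biological explanation was tested.

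Smooth muscle genes were lower in Sox17+/- gallbladder over both strains by camera at its preset correlation (median -0.17 log2; adjusted p = 0.489 with an estimated correlation). A lower share of mesenchymal cells could lower fibroblast genes alike. These lay 0.18 log2 above smooth muscle genes (95% interval 0.01 to 0.32). That interval resamples genes, which vary together within a list, and not samples, so it cannot decide. In cystic duct, too, the smooth muscle and fibroblast medians fell unequally (-1.53 and -0.53). Dilution by carried-over liver or muscle would lower biliary epithelium genes alike; they lay 0.16 above (95% interval -0.05 to 0.45), and since that interval includes 0, dilution cannot be told apart from a change in the muscle cells.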

How the results depend on the processing

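The signature without members of the fixed lists was chosen after seeing the data, though before its own result; the other alternatives were set before the data were examined. The fall of Sox17 over both strains, tested over its 2 probe sets alone, and the gallbladder-high signature in B6 kept their direction and side of the threshold in every alternative run for them. In ICR that signature (-0.42) equals the value of simulated unchanged groups that share the wild type samples (-0.42). Those draws picked genes on noise alone, so how much sharing adds to the real value is not known. The stability of the ICR value therefore cannot speak for a shift. Over all genes Sox17 passed in 3 of 10 fits without 1 sample and in 3 of 9 other settings. Where counts of genes moved, the cause was not tested unless given. With the values as deposited the counts were 2 for ICR, 2 for B6 and 54 for strain; with medians centred 0 for ICR and 0 for B6. No filter gave 5 over both strains. The mean of probe sets gave 3 for ICR and 33 for strain. Every probe set on its own, which adds tests, gave 2 over both strains and 664 for strain, and no trend gave 2 over both. Array weights gave 136 over both strains, 5 for ICR, 103 for B6, 0 for cystic duct and 1195 for strain. With only the groups compared, which changes the samples in the variance estimate, these were 78, 2, 49, 0 and 296. With an estimated inter-gene correlation 0 gene lists passed in the comparisons over both strains, ICR, B6, the strain difference and cystic duct (7, 4, 6, 4 and 8 before), and the cystic duct-high signature no longer passed at unchanged medians of 0.23 in B6 and 1.01 in ICR.

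With the replicate number as a block the counts were 1 over both strains, 0 for ICR, 0 for B6 and 13 for strain. Samples share only a number: same-numbered deviations correlated at 0.377, 0.0748, 0.0873 and 0.217, and no label ties a number to a litter or day.

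Leaving out 1 sample, which also removes degrees of freedom, gave 1 to 281 genes over both strains, 0 to 377 for ICR, 0 to 5 for B6, 0 to 270 for the strain difference, 813 to 7531 for cystic duct and 0 to 614 for strain. Gene lists ranged from 4 to 11 over both strains, 2 to 8 for ICR and 2 to 8 for the strain difference. The cystic duct-high median in B6, with its genes chosen anew in each fit, ranged from 0.0083 to 0.45, and the correlation of strains from 0.132 to 0.387.

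Among genes named, 11 values turned sign, 9 of them because another probe set then had the highest mean. Shh in the strain difference was -0.49 with the mean of probe sets. Leaving out 1 sample, Htr1b in cystic duct ranged from -4.09 to 0.070, Eif5b in strain from -2.18 to 2.31 (1.01 and 2.31 without ICR wild type replicate 1 or 2), Ywhab in the strain difference from -0.72 to 0.22 (0.09, 0.20, 0.14, 0.16, 0.13 and 0.22 in 6 fits) and Gli1 in B6 from -0.25 to 0.047. Of the other values of named genes, 2687 kept direction and side of the threshold, 373 no longer passed and 176 newly passed. The floor alternatives were not run, as the values are already log2. Genes near the lowest signal of 2.20 cannot show further falls.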

Other observations

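The test of the Hedgehog targets and the gene calls of the fit with gallbladder samples alone were singled out after their results were seen; the tests of other splits and of the signature without list members were not. In that fit, 78 genes passed over both strains by limma, 31 higher and 47 lower. Those higher included Olfm4 (1.80 log2, adjusted p = 0.0329), Tspan8 (1.70, 0.00403), the tight junction gene Cldn8 (1.63, 0.0389), Spink4 (1.56, 0.0473), the phosphate transporter Slc34a2 (1.44, 0.0125), Cdh16 (1.24, 0.0112), Clu (1.14, 0.0458) and Agr2 (0.75, 0.0329), with the endoderm factors Pdx1 (1.40, 0.0332) and Hhex (0.75, 0.0329). Also higher were Ces1d (1.25, 0.0434), Cfi (1.19, 0.0371), Lect2 (1.18, 0.0142), Serpina1b (1.15, 0.0329) and Cpn1 (0.75, 0.0389), which hepatocytes express, and 11 of the 20 hepatocyte list genes passed in this fit adjusted over the list alone. In the fit of all samples Pdx1 stood at 0.72 and Cpn1 at 0.34 with the mean of probe sets. Those lower included the brush border enzyme Mgam (-2.35, 0.0141), Cyp2f2 (-1.89, 0.00244), the calcium-binding S100g (-1.86, 0.0154), Cox7a1 (-1.52, 0.00379), the cholecystokinin receptor Cckar (-1.49, 0.0329), the Wnt genes Porcn (-0.95, 0.0371) and Fzd7 (-0.70, 0.0121), and Foxf1 (-0.53, 0.0437). Porcn and Fzd7 are not in the fixed Wnt list, of whose 16 measured genes 0 passed in this fit by either adjustment. The calls of this fit rest on a variance estimated without the cystic duct pair, and in the fit of all samples only 8 genes passed.

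Other splits of the 8 gallbladder samples were counted for the genotype effect over both strains. Of 34 splits, 5 gave at least the real 8 genes, the real one included, and the highest other gave 255, so chance cannot be excluded by this count. The other 4 call many times more genes than the real split and each sets ICR wild type gallbladder replicate 1 apart, which points to a structure of that sample. Among the 18 splits balanced over strains, 1 gave as many, the real one, and the others gave 0. With 18 splits the share with as many genes could not fall under 0.05, so this count could not exclude chance whatever its outcome. A value of another kind goes against chance for part of the result: Cited1 was called in each strain on its own, against 6.8e-05 genes for independent lists. Both of its tests used the same variance estimate, so they were not fully independent. The strains' changes correlated at r = 0.270, against -0.02 to 0.03 in simulated unchanged groups. Real genes vary together, with an estimated correlation of 0.76 in the erythroid list, so this range may be too narrow to bear on chance. The call of Cited1 bears on that gene, not on each of the 8.

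In ICR wild type gallbladder replicate 1, 538 genes were over 1 log2 unit lower and 71 higher than in replicate 2, and 521 of the 538 lay below all 7 other gallbladder samples. Their median genotype change was 1.15 log2 in ICR and -0.04 in B6. Fits without replicate 2 rest on replicate 1 alone for ICR wild type gallbladder. The mostly 1-sided calls of those fits therefore point to replicate 1, not to replicate 2.

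One hypothesis was that Hedgehog targets respond less in B6 than in ICR although Shh falls alike. Shh differed by 0.29 log2 between strains (SE 0.65), while Ptch1 stood at -0.82 in ICR and -0.17 in B6, Gli1 at -0.84 and -0.10, Hhip at -1.91 and -1.48, and Foxf1 at -0.87 and -0.20. By fry, a rotation test in limma, the 4 targets as a set gave a probability of 0.0222 before adjustment, on targets singled out after their values were seen. Without B6 Sox17+/- replicate 3 or 4 the B6 values were -0.02 and -0.32 for Ptch1, 0.05 and -0.25 for Gli1 and -0.04 and -0.35 for Foxf1, and the strain difference was 0.69 and 0.16 for Hhip and 0.49 and 0.09 for Shh. Without ICR Sox17+/- replicate 1 it was 0.39 for Ptch1 and 0.18 for Shh. Foxf1 is the target with the clearest difference (0.67, SE 0.18), and its other probe set gave -0.04 on this contrast. With the mean of probe sets the strain difference was -0.49 for Shh, 0.71 for Hhip, 0.35 for Ptch1 and 0.32 for Foxf1, and Foxf1 stood at -0.34 in B6. With each sample centred on its median that difference was 0.17 for Shh and 0.27 for Hhip, and Gli1 stood at -0.17 in B6. No single target passed in limma over all genes, so the hypothesis stays open.

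Another hypothesis was that the gallbladder-high genes are lower in B6 Sox17+/- gallbladder only through members of the fixed lists. Without these, 87 genes remained, with a median of -0.20 log2 and 73 below 0 (camera p = 0.0277 with an estimated correlation), which argues against it. The cystic duct-high genes without list members had a median of 0.22 in B6 (camera p = 0.426 with an estimated correlation). Most of these remaining genes still encode plasma proteins, liver enzymes or blood cell proteins. The full set lay outside the range of simulated unchanged groups (0.23, range -0.14 to 0.11). Its estimated correlation was 0.62, and with that the set did not pass, so the range may be too narrow. The full set's median was 0.04 without B6 wild type replicate 4 and 0.01 without ICR wild type gallbladder replicate 2, both inside the range. The genes of the set were chosen anew in each of these fits. Dilution of gallbladder by carried-over tissue would also lower gallbladder-high genes, and no test here separates it from a shift towards cystic duct.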
